A study of Homo sapiens with 20 samples.

How the data were processed

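Total RNA was sequenced from exosomes and from cytoplasmic RNA granules of HEK293 cells, a human embryonic kidney line. Cells were either controls or HD-induced, where HD stands for Huntington's disease. How the disease state was induced is not given in the sources used here. Each of the 4 groups held 5 libraries, which the study describes as biological replicates. Per the labels, RNA was isolated with a mirVana kit, and stranded total RNA libraries were read in pairs of 100 bases on a NovaSeq instrument.

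The authors trimmed and filtered the reads and quantified transcripts against build GRCh38.p14. Their notes name Trimmomatic, cutadapt, FastQC and Salmon, and the tool versions and the annotation release are not given in the sources used here. Each deposited file held, for every transcript, an expected count (the estimated number of reads, not a whole number) and a TPM value (transcript abundance relative to its library, corrected for length). The values were checked: TPM summed to its defining total in each of the 20 libraries. Each file listed 921552 entries, of which 251955 were named transcripts of 62266 genes and 669597 were entries with a sequence identifier but no gene, symbol or class. The latter are called unnamed entries. Reads on unnamed entries counted toward depth and class shares but not toward gene tests. Because named genes and unnamed entries can hold the same sequence, the level of a small RNA gene can depend on how reads were divided between them.

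Expected counts were summed over the transcripts of each gene and rounded. Genes were kept by filterByExpr, libraries were scaled with trimmed means of M values (TMM), and groups were compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. P values were adjusted with the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels of genes are TMM-scaled CPM (counts scaled to a common library size) unless stated otherwise, and they can be compared only within one comparison. The 5 comparisons were granules against exosomes in control cells, the same in HD-induced cells, HD-induced against control in exosomes, the same in granules, and the difference between the last 2 effects (an interaction term over all 20 libraries).

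The rule for named genes took, per direction, the 10 called genes with the largest fold change among protein-coding and lncRNA genes with an official symbol, a mean of at least 5 CPM in either group, and all 5 libraries of one group above all 5 of the other. Where no gene passed, it took the 5 with the smallest p per direction. It also took HTT, up to 4 members of each gene list with the smallest p, the 5 genes with the highest mean TPM per group, and the called genes of the interaction. Some genes that the rule took are not reported. After the data were seen, the rule was repeated without HD exosome 4. Gene positions are from the reference annotation of build GRCh38.p14, counted from 1.

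For genes, 32 lists were fixed: proteins of stress granules, proteins of P-bodies, exosome biogenesis and markers, reference transcripts of stress granules, translation mRNAs with a 5' terminal oligopyrimidine tract, nuclear lncRNAs, cytoplasmic lncRNAs with snoRNA hosts, structured cytoplasmic RNAs, Huntington-related genes, the unfolded protein and integrated stress response, heat shock chaperones, autophagy and lysosome, interferon response, p53 and DNA damage, cholesterol biosynthesis, immediate early genes, cell cycle, neuronal genes, glycolysis, serum with blood and liver, leukocytes, fibroblasts with endothelium, cytosolic ribosomal proteins, mitochondrial mRNAs, mitochondrial rRNAs with tRNAs, nuclear-encoded respiratory chain, mitochondrial ribosomal proteins, spliceosomal snRNAs, snoRNAs with scaRNAs, replication-dependent histones, the proteasome and zinc finger transcription factors. A list needed 3 tested members. The lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, and adjusted over 123 tests of 31 lists in 4 comparisons. The tests were repeated with an estimated correlation and with fry. Counts of called members are given over all genes tested and as adjusted over the list alone.

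Shares of 11 RNA classes were taken over all estimated reads and compared by exact 2-sided permutation tests, adjusted over 44 tests. A gene was counted as detected in a group when its TPM was at least 1 in all 5 libraries. Spearman's rho of the log2 fold change with the median transcript length, and with the GC content of transcripts, was taken across tested protein-coding genes, which are not independent replicates. GC content was read from GENCODE release 29 sequences. Where a group held no read of a gene, the fold change was bounded by a floor of 3 counts over the group. Intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only.

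The pipeline was tested on simulated data in which 200 genes were changed. At 4-fold it recovered 100% of changed genes for granules against exosomes in control cells, 56% in HD-induced cells, 96% for HD-induced against control exosomes, 84% for granules and 36% for the interaction. At 2-fold the shares were 59%, 1%, 24%, 13% and 1%. The simulation gave all genes of a comparison the same spread and changed only genes at 5 CPM or more. It multiplied depth by the TMM factor, so HD exosome 4 was simulated deeper than it was. The shares are therefore not the power of the tests on the real libraries. Among 40 pairs of libraries of one group, 0 were identical.

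The groups, comparisons, lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives were other size factors, DESeq2 1.42.0, limma on log2(TPM + 1), voom with quality weights, other filters, protein-coding genes alone, length-scaled counts, thinning, a 2-fold minimum, a replicate block, 1 surrogate variable from sva 3.50.0, a fit of all 20 libraries and leaving out each library in turn. After the data were seen, a correction for GC content, fits without HD exosome 2, HD exosome 4 and HD granule 3, and lists of keratinocyte markers and of mRNAs that localise to cell protrusions were added. All 20 libraries were kept in the reported comparisons. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.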

Results

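Total RNA was measured by sequencing in exosomes, small vesicles that cells release, and in cytoplasmic RNA granules, assemblies of RNA and protein without a membrane that the labels call granule cores. Both came from HEK293 cells, a human embryonic kidney line, in a control state and in an HD-induced state meant to model Huntington's disease, which is caused by a repeat expansion in HTT. The 20 libraries formed 4 groups of 5 replicates: control exosomes, HD-induced exosomes (HD exosomes below), control granules and HD-induced granules (HD granules). The design text states the aim of exploring and comparing the RNA content of both compartments in normal and Huntington cells, so granules were compared with exosomes within each state, HD-induced with control within each compartment, and the HD effects of both compartments with each other.

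Depth, as the sum of estimated reads per library in mega-reads (M), was higher in granules than in exosomes. Control exosomes 1 to 5 held 15.6, 14.1, 10.97, 8.99 and 10.3 M reads, and control granules held 17.4, 34.5, 23.96, 38.4 and 18.8 M. HD granules held 26.96, 34.4, 35.8, 34.996 and 31.7 M. HD exosomes were uneven, at 12.1 M for replicate 1, 14.4 M for replicate 2, 1.98 M for replicate 3, 1074 reads for replicate 4 and 4.25 M for replicate 5. Reads on named genes numbered 5.30 to 9.04 M in control exosomes, and 7.41, 1.94 and 1.33 M, 713 reads and 3.00 M in HD exosomes 1 to 5. HD exosome 4 showed 544 genes with at least 1 read and 1 gene with at least 10. In HD exosome 2, 86.6% of reads (Wilson 95% interval 86.5% to 86.6%) lay on unnamed entries, against 24.9% to 59.2% in the other 19 libraries.

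**Figure D1:**
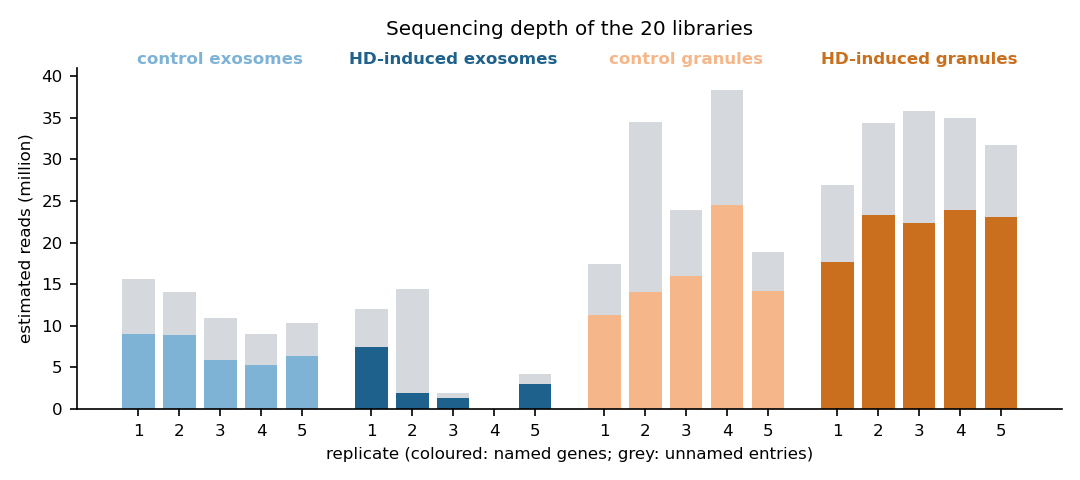
Estimated reads per library in M, with reads on named genes in colour and reads on unnamed entries in grey, for 4 groups of 5 replicates. HD exosome 4 held 1074 reads, and in HD exosome 2 unnamed entries took 86.6%.

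Shares of reads were compared between groups for 11 RNA classes. SnoRNAs and scaRNAs, which guide chemical modification of other RNAs in the nucleolus and Cajal bodies, took 0.988% ± 0.184 (SD, n = 5) of control granule reads and 0.0177% ± 0.00519 of control exosome reads, a ratio of 55.97. In HD-induced cells the means were 1.25% ± 0.711 in granules and 0.0134% ± 0.00819 in exosomes, and the lowest granule value, 0.0641% (Wilson 95% interval 0.0633% to 0.0650%), was that of HD granule 3. Ribozyme RNAs, mainly the RNA parts of RNase P and RNase MRP, took 2.06% ± 0.464 of control granule reads and 0.747% ± 0.165 of control exosome reads, and miscellaneous RNAs took 0.0605% ± 0.0175 and 0.0161% ± 0.00468. SnRNAs, parts of the splicing machinery, took 0.809% ± 0.221 of control exosome reads and 0.274% ± 0.203 of HD exosome reads. In control cells, nuclear-encoded mRNA took 55.9% ± 3.90 of exosome and 56.7% ± 12.4 of granule reads, and unnamed entries took 40.9% ± 3.65 and 37.6% ± 12.8. None of 44 class tests passed. With 5 against 5 libraries the exact permutation p is 0.00794 at best. This was reached by 5 of the tests above and became 0.0698 after adjustment over the 44. Without HD granule 3, and with shares of named-gene reads, 7 tests passed in each case.

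**Figure D2:**
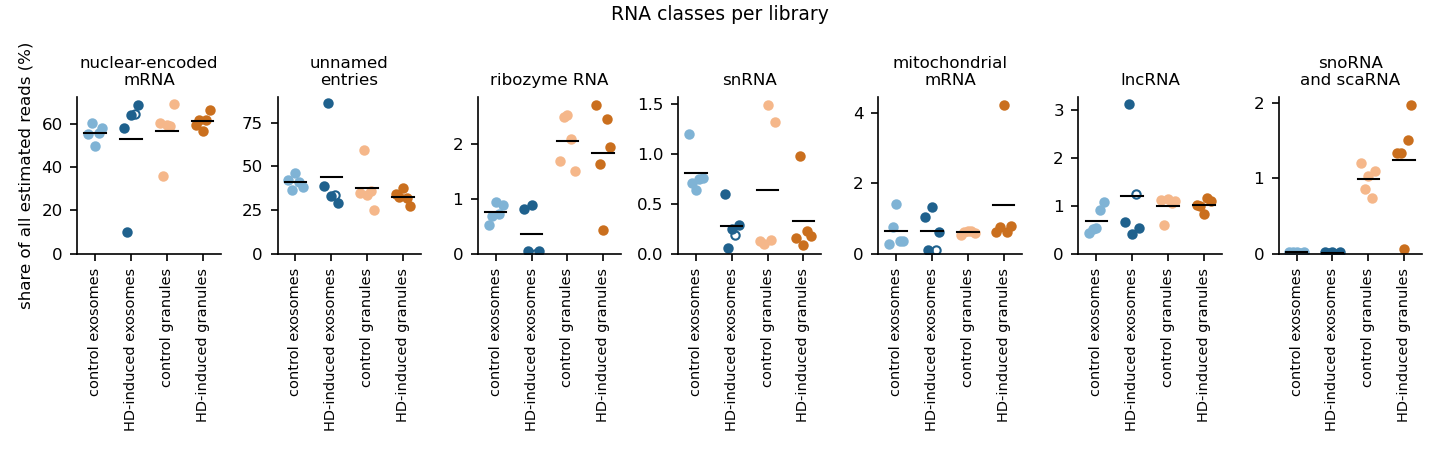
Share of all estimated reads in percent by RNA class and library, on a linear scale of its own for each class, with a line at each group mean and HD exosome 4 as an open circle. The share of snoRNAs and scaRNAs was 0.988% in control granules and 0.0177% in control exosomes on average.

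Of the 5 genes with the highest mean TPM in each group, all but ENSG00000280800, an lncRNA, and RPL39, a ribosomal protein mRNA, were small structured RNAs. RNU1-1, the U1 snRNA, stood at 38744 ± 13425 TPM (SD, n = 5) in control exosomes and at 58705 ± 80420 in control granules, where single libraries ranged from 0 to 150140. RPPH1, the RNA of RNase P, stood at 19964 ± 5286 TPM in control exosomes, 41946 ± 6567 in control granules, 10569 ± 14176 in HD exosomes and 33231 ± 12662 in HD granules. RNVU1-7, RN7SK and a Y RNA followed in control exosomes, and RNY1, RNVU1-7 and ENSG00000280800 were also among the first 5 in HD exosomes. SCARNA10 and RMRP were among the first 5 in both granule groups, with RNU4-2 in control granules and RPL39 in HD granules. Reads of such RNAs can pass to unnamed entries of like sequence: RNU1-1 stood at 0 in some libraries of 3 groups.

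At a TPM of at least 1 in all 5 replicates, 9887 genes were detected in control exosomes and 9261 in control granules. Of these, 8565 were shared, 86.6% of those in exosomes, and 8399 of the shared genes were protein coding. A further 1322 genes were detected in all control exosomes but not in all control granules, and 696 the other way. Which compartment held more genes depended on the cutoff. At a TPM of at least 0.5 the unshared genes numbered 893 in control exosomes and 898 in control granules. At 10 expected counts, which are not scaled for depth, they numbered 246 and 2292. In HD-induced cells 393 genes were detected in exosomes, 8738 in granules and 391 in both. Without HD exosome 4 these became 4114, 8738 and 4040, and without HD exosome 2, HD exosome 4 and HD granule 3 they became 9962, 8893 and 8146.

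In control cells, granules and exosomes carried strongly different RNA. Higher in granules were 80 of 83 snoRNAs and scaRNAs and 12 of 18 snoRNA hosts and cytoplasmic lncRNAs. Higher in exosomes were 14 of 20 mRNAs of glycolytic enzymes, 18 of 31 of the proteasome and 20 of 34 of exosome biogenesis and markers. As groups, these 5 lists passed with a preset correlation between genes and missed the threshold at adjusted p 0.421 to 0.801 with an estimated correlation. The mean of CDR1 rose from 8.88 ± 4.97 CPM (SD, n = 5) in exosomes to 291 ± 107 in granules, with a fitted fold change of 33.0. MYL9 mRNA, which encodes a myosin light chain, was at 27.9 ± 11.6 CPM in exosomes and 0.186 ± 0.0497 in granules. HTT mRNA differed by a log2 fold change of 0.04 ± 0.15 (SE; 183 CPM in exosomes, 188 in granules; adjusted p 0.836), with a 95% interval of -0.25 to 0.32, and it passed with the GC correction described below (0.35; adjusted p 0.0291). Of 14777 genes tested, 9227 differed, 4431 higher in granules and 4796 higher in exosomes, and 5518 of them differed at least 2-fold. Which direction held more calls is not fixed, as 4964 were higher in granules and 4365 in exosomes with RLE size factors, 5053 and 4304 with upper-quartile factors, and 6178 and 5026 with DESeq2.

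Among the 10 named genes highest in granules (log2 fold change of granules over exosomes ± SE, n = 5 and 5), ASH1L-AS1, an antisense transcript at chromosome 1, 155562042 to 155563944 of GRCh38.p14, had no read in control exosomes and 15.2 CPM in control granules, at least 182-fold higher. N4BP2L2-IT2, an intronic transcript, stood at 5.43 ± 0.52 and UBL7-DT, a divergent transcript, at 3.86 ± 0.68. SNHG29 (chromosome 17, 16438987 to 16470648), a snoRNA host, rose from 5.63 to 124 CPM, a log2 fold change of 4.49 ± 0.69. Transcripts of 3 bitter taste receptor genes, TAS2R14, TAS2R46 and TAS2R30, stood at 5.24 ± 0.62, 4.43 ± 0.69 and 4.34 ± 0.49. CLDN1, a tight junction gene, stood at 4.08 ± 0.94, and HELLPAR, a long noncoding RNA, at 3.95 ± 1.22. Without a count filter HELLPAR had an adjusted p of 0.0650.

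Of the 10 named genes highest in exosomes, RPL10L, a retrocopy-derived paralog of RPL10 (chromosome 14, 46651010 to 46651781), was at 21.5 CPM in exosomes with no read in granules, at least 582-fold. RGS18, a regulator of G protein signalling in blood cells, was at least 182-fold higher, from 6.85 CPM. ALAS2, which encodes the heme synthesis enzyme of red blood cells (chromosome X, 55009055 to 55030977), stood at -8.32 ± 0.60, from 23.6 CPM in exosomes to 0.0658 in granules. KRT5, a keratin of basal skin cells (chromosome 12, 52514575 to 52520394), stood at -7.002 ± 1.03, and MYL9 (chromosome 20, 36541519 to 36551447) at -7.14 ± 0.45. The histone genes H3-4 and H3C7 stood at -8.12 ± 0.76 and -7.46 ± 0.84, ZNF90 at -7.82 ± 0.77, and the POTE family members POTEE and POTEI at -7.50 ± 0.71 and -7.08 ± 0.60. Reads of RPL10L, POTEE, POTEI and histone genes can be shared with near-identical relatives.

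SnoRNAs and scaRNAs moved together: 80 of 83 tested were higher in control granules and 0 lower, also 80 when adjusted over the list alone, with a median log2 fold change of 5.45, or 5.03 with 15 members that had a group at 0 set to their bound. The list passed the test across lists (adjusted p 6.5e-21, and adjusted p 0.421 with an estimated correlation). Where in the cell the snoRNAs and scaRNAs of the granule preparations came from was not tested. SCARNA5 rose from 18.4 to 1560 CPM (6.41 ± 0.24, SE), and SCARNA13, SNORD15B and SCARNA6 stood at 6.15, 6.39 and 5.08. Of 18 cytoplasmic lncRNAs and snoRNA hosts, 12 were higher and 2 lower, the same counts as adjusted over the list alone, with a median of 1.21 (adjusted p 0.00568, and adjusted p 0.502 with an estimated correlation). GAS5 rose from 143 to 1502 CPM (3.40 ± 0.14), and SNHG1, ZFAS1 and SNHG5 stood at 3.04, 3.53 and 2.41. Cytosolic ribosomal protein mRNAs leaned to granules, with 41 of 79 higher and 14 lower (42 and 15 adjusted over the list alone; median 0.71; adjusted p 0.00684, and adjusted p 0.801 with an estimated correlation), from RPS27 at 2.17 and RPS29 at 1.90 to RPL7A at -1.93 and RPL28 at -2.07. Nuclear-encoded respiratory chain mRNAs did likewise, with 45 of 77 higher and 19 lower (47 and 19 adjusted over the list alone; median 0.87; adjusted p 0.00436, and adjusted p 0.801 with an estimated correlation), from COX7A2 at 2.13 and NDUFB3 at 1.72 to UQCRC1 at -2.29.

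On the exosome side stood 14 of 20 glycolytic mRNAs, with 1 higher in granules (1 and 14 also adjusted over the list alone; median log2 fold change -1.94; adjusted p 1.71e-05, and adjusted p 0.739 with an estimated correlation). ENO1 was at 3136 CPM in control exosomes and 569 in control granules (-2.46 ± 0.11, SE), PKM at 1220 and 149 (-3.04 ± 0.17), GPI at -2.95 and PGAM1 at -2.29. Of 34 genes of exosome biogenesis and exosome markers, 20 were higher in exosomes and 2 in granules (21 and 3 adjusted over the list alone; median -0.72; adjusted p 0.00208, and adjusted p 0.739 with an estimated correlation), among them FLOT1 at -1.98, CHMP4B at -1.91, VPS4A at -1.64 and ANXA2 at -1.58. The mRNAs encoding proteins of stress granules were also mostly higher in exosomes, 27 of 43, with 5 higher in granules, the same as adjusted over the list alone (median -0.47; adjusted p 0.00373, and adjusted p 0.799 with an estimated correlation). YBX1, an RNA-binding protein gene, was at 1712 CPM in exosomes and 196 in granules (-3.13 ± 0.17), and ELAVL1, TAF15 and IGF2BP1 stood at -1.83, -1.52 and -1.19. Of 31 proteasome mRNAs, 18 were higher in exosomes and 5 in granules, the same as adjusted over the list alone (median -0.81; adjusted p 0.0143, and adjusted p 0.801 with an estimated correlation), with PSMD3 at -2.55, PSMC4 at -2.24, PSMC3 at -1.98 and PSMD4 at -1.88.

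The other 23 lists did not pass the list test in control cells, although many of their members differed (counts are members higher in granules and in exosomes). Huntington-related genes gave 12 and 15 of 38, with a median log2 fold change of -0.03, as ZDHHC17 (1.27 ± 0.11, SE) and REST (1.01 ± 0.11) were higher in granules, and NAA10 (-2.44 ± 0.22) and PFN2 (-1.71 ± 0.17) in exosomes. P-body protein genes gave 13 and 17 of 39, with AGO1 at -2.47 and LSM5 at 1.24. The unfolded protein and integrated stress response gave 16 and 8 of 36, with SEL1L at 2.67 and PHGDH at -1.79. Heat shock chaperones gave 5 and 14 of 28 (adjusted p 0.0674), with FKBP4 at -1.88, and autophagy and lysosome genes 6 and 18 of 35 (adjusted p 0.0736), with ATP6V0D1 at -2.50. Genes of p53 and DNA damage gave 5 and 14 of 25, cholesterol biosynthesis 6 and 13 of 27, immediate early genes 4 and 13 of 26, cell cycle genes 11 and 21 of 36, and interferon response genes 3 and 5 of 20. Translation mRNAs with a 5' terminal oligopyrimidine tract gave 7 and 12 of 25, mitochondrial ribosomal proteins 22 and 26 of 78, zinc finger transcription factors 154 and 108 of 431, and histones 25 and 18 of 51 with a median of 0.49 and a mean of -0.49. Nuclear lncRNAs gave 4 and 0 of 7, with MALAT1 at 0.85, spliceosomal snRNAs 10 and 1 of 16, mitochondrial mRNAs 6 and 1 of 13, and structured cytoplasmic RNAs 3 and 1 of 7 with a median of 1.23, unchanged with 2 members at their bound. Of the 4 reference transcripts of stress granules, DYNC1H1 and ZNF704 were higher in granules and AHNAK (-2.37 ± 0.17) in exosomes.

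No list of markers for other cells or tissues passed in control cells, although most serum, blood and liver genes were called higher in exosomes. The source of those transcripts was not tested. Serum, blood and liver genes gave 0 and 6 of 7 (median log2 fold change -2.58; adjusted p 0.117), with HBG1 at -2.98, HBA1 at -2.86 and HBB at -2.58 beside ALAS2. Neuronal genes gave 4 and 8 of 16, fibroblast and endothelial genes 2 and 4 of 10, with COL1A2 at -6.71, and leukocyte genes 0 and 1 of 3, with PTPRC at -3.35. Mitochondrial rRNAs and tRNAs had too few reads to test. The counts adjusted over the list alone differed for 4 of these 23 lists, at 11 and 22 for cell cycle, 5 and 8 for neuronal genes, 1 and 1 for leukocytes and 26 and 18 for histones. The medians of Huntington-related, interferon, mitochondrial ribosomal protein and P-body lists changed sign with other size factors. Those factors moved the median of all genes from -0.02 to 0.09 (RLE), 0.10 (DESeq2) or 0.11 (upper quartile), so list medians within that distance of 0 have no direction.

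**Figure D3:**
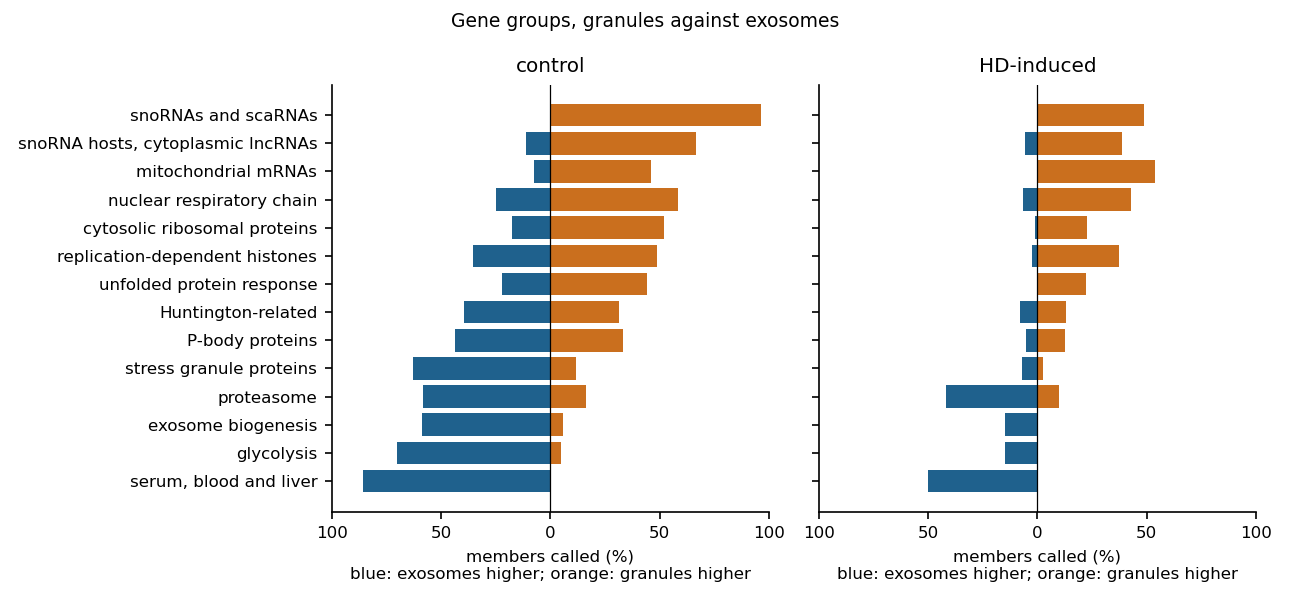
Percent of tested members of each gene list called higher in granules and higher in exosomes, for control and HD-induced cells. In control cells 80 of 83 snoRNAs and scaRNAs were higher in granules and 14 of 20 glycolytic mRNAs higher in exosomes.

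In HD-induced cells 35 of 72 snoRNAs and scaRNAs were higher in granules, and 13 of 31 proteasome mRNAs were higher in exosomes. The mRNA of RAB13, a small GTPase, was 41.1-fold higher in HD exosomes (log2 fold change -5.36 ± 0.52, SE, n = 5 and 5; chromosome 1, 153981650 to 153990708), and that of NET1, an exchange factor for RhoA, 10.4-fold higher (-3.38 ± 0.49; chromosome 10, 5412557 to 5459056). SNHG29 (4.99 ± 0.95) and TAS2R46 (5.58 ± 1.09) were higher in granules, as in control cells. SNHG29 lost its call with a block of replicate numbers (adjusted p 0.0965) and TAS2R46 with DESeq2 (adjusted p 0.0528). HTT stood at -0.02 ± 0.35 (adjusted p 0.976). Of 14431 genes tested, 2553 differed, 1720 higher in granules and 833 higher in exosomes.

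The other named genes higher in HD granules were noncoding transcripts and TICAM2, an adaptor of Toll-like receptor signalling. With no read in HD exosomes, TICAM2 was at least 37.1-fold higher, PCGF3-AS1 29.96-fold, SPAG5-AS1 22.8-fold, TNRC6B-DT 17.9-fold and PRDM10-DT 15.95-fold, each as a lower bound. PCAT19, USP34-DT and EOLA1-DT had log2 fold changes of 5.88 ± 1.12, 5.82 ± 1.04 and 4.97 ± 0.81 (SE). These 3, TICAM2, PCGF3-AS1 and PRDM10-DT lost their calls in voom with quality weights (adjusted p 0.0698 to 0.204). On the exosome side KRT1, a keratin of the outer skin layers (chromosome 12, 52674736 to 52680407), stood at -6.95 ± 1.01. The translation factor genes EIF3I and EIF6 stood at -2.16 ± 0.34 and -2.09 ± 0.30, the mitochondrial ribosomal protein gene MRPS11 at -2.003 ± 0.29, and the mitochondrial enzyme gene HSD17B10 at -2.27 ± 0.30. CDKN2AIPNL and SAMD4A stood at -2.67 ± 0.35 and -1.83 ± 0.25, and SAMD4A lost its call with length-scaled counts (adjusted p 0.232). With limma on log2(TPM + 1), NET1 and the exosome-side genes of this paragraph other than KRT1 lost their calls (adjusted p 0.271 to 0.801), as did PCGF3-AS1, USP34-DT and EOLA1-DT (adjusted p 0.0627 to 0.168).

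HD exosome 4 decided which genes could be named on the exosome side, because its 713 reads on named genes left most genes at 0 there. With it, 728 genes of granules and 29 of exosomes met the naming rule, and without it, 664 and 890. Without it, the exosome side was led by KRT6B (at least 680-fold), RPL10L (at least 487-fold), RGS18 (at least 360-fold), ALAS2 (log2 fold change -9.25), KRT6A (-9.15), KRT16 (-8.37), CALML5 (-8.34), KRT5 (-8.05), DSG1 (-7.87) and PKP1 (-7.59), of which all but RPL10L, RGS18 and ALAS2 are skin epithelial genes. The granule side was then led by P3R3URF-PIK3R3 (at least 74.998-fold), TICAM2, PCGF3-AS1, SPAG5-AS1, PSMA3-AS1 (at least 20.5-fold), PCAT19 (5.83), USP34-DT (5.78), SNHG29 (4.92), CDR1 (4.69) and PIERCE2 (4.64).

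Of the 8 lists that passed in control cells, 7 passed in the same direction in HD-induced cells, and the stress granule protein genes did not, with 1 higher in granules and 3 in exosomes of 43 (0 and 1 adjusted over the list alone; adjusted p 0.224). Without HD exosome 2, HD exosome 4 and HD granule 3 (the doubted libraries below, chosen after their values were seen), those genes gave 2 and 14 of 43 (adjusted p 0.00851, and unadjusted p 0.1995 with an estimated correlation). Of 72 snoRNAs and scaRNAs, 35 were higher in granules and 0 lower (38 and 0 adjusted over the list alone; median log2 fold change 3.59; adjusted p 0.000449, and adjusted p 0.801 with an estimated correlation), with SNORD13 at 10.26 ± 1.39 (SE), SCARNA5 at 6.997 ± 0.91, SNORA74A at 6.69 and SCARNA6 at 4.996. Among snoRNA hosts and cytoplasmic lncRNAs 7 of 18 were higher and 1 lower (9 and 1 adjusted over the list alone; median 1.99; adjusted p 0.00373, and adjusted p 0.798 with an estimated correlation), with GAS5 at 3.80 and SNHG1 at 2.11 (adjusted p 0.208 with length-scaled counts). Cytosolic ribosomal protein mRNAs gave 18 higher and 1 lower of 79 (26 and 3 adjusted over the list alone; median 1.29; adjusted p 0.00155, and adjusted p 0.801 with an estimated correlation), with RPS27 at 2.80, RPS21 at 2.73, RPS29 at 2.59 and RPL28 at -1.56, which lost its call in 5 fits without 1 library (adjusted p 0.0507 to 0.0554). The nuclear-encoded respiratory chain gave 33 higher and 5 lower of 77 (41 and 10 adjusted over the list alone; median 1.19; adjusted p 0.00373, and adjusted p 0.801 with an estimated correlation), with COX6A1 at 3.53, NDUFA1 at 3.03, NDUFS4 at 2.99 and NDUFB9 at 2.43. Without the doubted libraries 93 of 116 snoRNAs and scaRNAs were higher in granules (median 6.62). Ribosomal protein mRNAs then gave 43 higher and 11 lower of 79, the respiratory chain 47 and 14 of 77.

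On the exosome side, 13 of 31 proteasome mRNAs were higher there and 3 in granules (18 and 5 adjusted over the list alone; median log2 fold change -0.92; adjusted p 5.19e-05, and adjusted p 0.798 with an estimated correlation), with PSMD8 at -1.98, PSMB6 at -1.92, PSMC4 at -1.66 and PSMC3 at -1.63. Glycolytic mRNAs gave 3 of 20 higher in exosomes (11 adjusted over the list alone, and 14 higher with a median of -1.87 without the doubted libraries; median -1.11; adjusted p 0.000637, and adjusted p 0.798 with an estimated correlation), TPI1 at -1.84, PGAM1 at -1.62 and PGK1 at -1.08. TPI1 lost its call in 7 fits without 1 library (adjusted p 0.0534 to 0.0774) and PGK1 in 8 (adjusted p 0.0510 to 0.0989). Exosome biogenesis and marker genes gave 5 of 34, also when adjusted over the list alone, and 15 of 36 without the doubted libraries (median -0.58; adjusted p 0.000476, and adjusted p 0.421 with an estimated correlation), among them SMPD2 at -1.62, CHMP4B at -1.44, ANXA2 at -1.40 and TSG101 at -0.99. SMPD2 lost its call in 7 fits without 1 library (adjusted p 0.0549 to 0.0732), with length-scaled counts (0.149) and with DESeq2 (0.127). TSG101 lost it in 4 such fits (0.0540 to 0.0578) and with DESeq2 (0.0652), CHMP4B with DESeq2 (0.0681), and ANXA2 without HD granule 1 (0.0502).

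A further 4 lists passed in HD-induced cells but not in control cells, and the difference between states was not tested for lists. All 4 missed the threshold without the doubted libraries, where the medians of histones and of serum, blood and liver genes stayed about as large. Mitochondrial mRNAs gave 7 of 13 higher in granules and 0 lower (8 and 0 adjusted over the list alone; median log2 fold change 2.69; adjusted p 0.00208, and adjusted p 0.798 with an estimated correlation; median 1.24 and adjusted p 0.146 without the doubted libraries), with MT-ND3 at 4.07 ± 0.51 (SE), MT-ATP6 at 4.05, MT-ND6 at 3.41 and MT-ND2 at 3.27. The unfolded protein and integrated stress response gave 8 of 36 higher and 0 lower (12 and 0 adjusted over the list alone; median 0.50; adjusted p 0.00373, and adjusted p 0.798 with an estimated correlation; median 0.19 and adjusted p 0.205 without the doubted libraries), with SEL1L at 2.43, DNAJB11 at 2.30, VLDLR at 2.26 and SLC7A11 at 2.11. Histones gave 16 of 43 higher and 1 lower (17 and 3 adjusted over the list alone; median 1.02; adjusted p 0.0449, and adjusted p 0.801 with an estimated correlation; 24 higher and 15 lower of 56, median 0.96 and adjusted p 0.123 without the doubted libraries), with H4C2 at 3.19, H2BC5 at 2.86, H3C1 at 2.78 and H4C5 at 2.76. Serum, blood and liver genes gave 3 of 6 higher in exosomes (5 adjusted over the list alone; median -3.72; adjusted p 0.0379, and adjusted p 0.798 with an estimated correlation; median -3.58 and adjusted p 0.0835 without the doubted libraries), HBG2 at -4.27 ± 0.91, HBB at -3.75 and HBG1 at -3.70. With a block of replicate numbers HBG1 and HBG2 lost their calls (adjusted p 0.0593 and 0.0689), as did HBB in voom with quality weights (0.158) and without HD exosome 5 (0.0542). Huntington-related genes gave 5 higher in granules and 3 in exosomes of 38, also when adjusted over the list alone (median 0.16; adjusted p 0.762), with HYPK at 1.52, ZDHHC17 at 1.47, ATXN1 at 1.19 (adjusted p 0.0522 without HD exosomes 2 and 4) and PFN2 at -1.60. Without the doubted libraries fibroblast and endothelial genes, cell cycle genes and spliceosomal snRNAs passed too (adjusted p 0.0132, 0.0429 and 0.0495). Their unadjusted p was 0.109 to 0.173 with an estimated correlation.

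The count of 2553 moved with the libraries kept. It was 5346 without HD granule 3, 1477 without HD granule 1, 1.2e+03 without HD granule 2, 1349 without HD granule 4 and 1240 without HD granule 5. It was 5758 (3065 higher in granules, 2693 in exosomes) without the 3 doubted libraries, and 4006 with a block of replicate numbers. With limma on log2(TPM + 1) 192 genes passed, and most genes and list members named for this comparison lost their calls. With RLE size factors 3036 genes differed, 81.0% of them higher in granules against 67.4% before, and the median of all genes moved from 0.17 to 0.32, so the balance between directions is not fixed by these data.

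Most calls in HD-induced cells were also made in control cells, where more genes were called. Of 14091 genes tested in both, 1597 were higher in granules in both states, out of 4277 such calls in control cells and 1686 in HD-induced cells (94.7% of these). If calls were independent, 512 would be shared. Higher in exosomes in both states were 805 genes, out of 4594 calls in control cells and 828 in HD-induced cells (97.2% of these), against 270 if independent. Opposite calls were made for 1 gene. Across genes, which are not independent replicates, the log2 fold changes of both states had a Spearman rho of 0.87 and a Pearson r of 0.81. The shared total of 2402 was 4967 without HD granule 3, and 1177 to 1475 without HD granule 1, 2, 4 or 5 or HD exosome 1 or 3. Those values were 1416, 1177, 1283, 1184, 1475 and 1456, in that order.

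**Figure D4:**
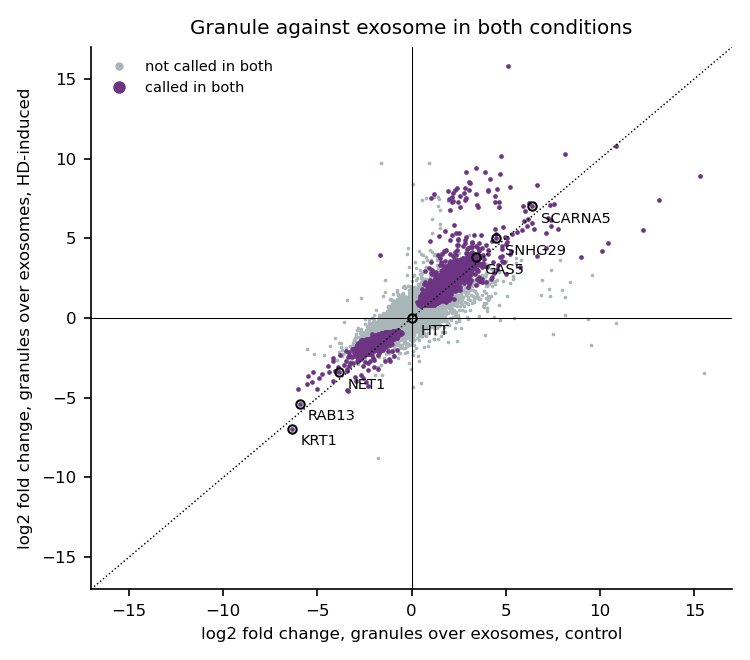
Log2 fold change of granules over exosomes in HD-induced cells (vertical) against control cells (horizontal), 1 point per gene tested in both. RAB13 and NET1 lie low on both axes and SCARNA5, SNHG29 and GAS5 high, and the Spearman rho was 0.87.

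HD-induced and control exosomes were compared to ask which RNAs the vesicles gain or lose in the disease state, and no gene passed the test. The smallest p was that of SNHG1, a snoRNA host (chromosome 11, 62851978 to 62855885), with a log2 fold change of HD-induced over control of 1.43 ± 0.27 (SE, n = 5 and 5) and an adjusted p of 0.482. TNC, an extracellular matrix gene, stood at 2.04 ± 0.47, NDUFAF2 at 1.32 ± 0.30, and the epithelial genes KRT17 and TRIM29 at 2.56 ± 0.63 and 2.79 ± 0.68. On the other side were NCBP2AS2 (-1.43 ± 0.35), ARFRP1 (-1.34 ± 0.35), CDAN1 (-1.08 ± 0.29), PPAN-P2RY11 (-2.94 ± 0.78) and EEFSEC (-1.002 ± 0.28), and all genes after SNHG1 had an adjusted p of 0.598. HTT stood at 0.23 ± 0.25 (adjusted p 0.735).

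With edgeR 0 of 12936 genes passed, 980 had an unadjusted p under 0.05, DESeq2 called 2 genes and limma on TPM values 22. A block of replicate numbers, which were not shown to pair libraries, gave 296 genes, among them SNHG1 (adjusted p 0.000498) and all genes named above by the rule but TNC, KRT17 and HTT. Without a filter 275 genes passed, and without HD exosome 1, the deepest HD exosome library on named genes, 497 passed, 74 higher and 423 lower, with an adjusted p of 0.000771 for SNHG1. When HD exosome 4 was left out, 1 gene passed, and the rule then also named KRT6B at 5.50, RPL32, RPL26 and RPL23 at 0.88, 0.89 and 0.76, SCAMP1 at -0.70, H2BC21 at -0.67, SPATA5L1 at -0.79 and TMEM250 at -5.01.

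Among gene groups, 49 of 52 histone genes had a lower estimate in HD exosomes, with 0 called, also adjusted over the list alone (median log2 fold change -0.44; adjusted p 0.000189, and adjusted p 0.798 with an estimated correlation), the first being H2BC15 at -0.84 ± 0.27 (SE), H2AC25 at -0.74, H2BC21 at -0.71 and H2BC17 at -0.58. Immediate early genes had 4 of 26 positive estimates and 0 calls, also adjusted over the list alone (median -0.36; adjusted p 0.00721, and adjusted p 0.801 with an estimated correlation; median -0.31 and adjusted p 0.0569 without HD exosomes 2 and 4), and zinc finger transcription factors had 249 of 415 positive and 0 calls, also adjusted over the list alone (median 0.12, and 0.04 without HD exosomes 2 and 4; adjusted p 0.0236, and adjusted p 0.801 with an estimated correlation). Serum, blood and liver genes had a median of 2.02 over 6 genes (adjusted p 0.0773; 0 called, 1 adjusted over the list alone), with HBG2 at 2.94 ± 0.88. Huntington-related genes had a median of -0.02 over 37 genes (0 called, also adjusted over the list alone; adjusted p 0.908). Without HD exosomes 2 and 4 a further 6 lists passed toward HD exosomes: ribosomal proteins (adjusted p 2.16e-09), terminal oligopyrimidine mRNAs (0.00188), mitochondrial mRNAs (0.00479, though their median was -0.02), and fibroblast and endothelial, interferon and cell cycle genes (0.0377 to 0.0495). Their unadjusted p was 0.0338 to 0.331 with an estimated correlation. Whether the lists of this paragraph leaned by the GC content of their members, described below, was not tested. Of 31 keratinocyte markers, a list written after keratins had been seen among the named genes, 15 could be tested, all 15 had a positive estimate with a median of 2.88, and 0 were called. Between compartments in control cells only 6 of them could be tested. Members that pass the count filter through high levels in HD exosomes lean positive by selection, so the shared sign is not support for an HD effect.

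HD-induced and control granules were compared with the same question, and again no gene passed. The smallest p among genes at 5 CPM or more was that of ANKRD1, a stress-responsive ankyrin repeat gene (chromosome 10, 90912096 to 90921087), at 33.0 CPM in control granules and 116 in HD granules, a log2 fold change of 1.81 ± 0.36 (SE, n = 5 and 5). TMSB10 stood at 1.11 ± 0.31, DUSP6, a phosphatase that acts on ERK, at 0.79 ± 0.22, PPP1R13B at 0.66 ± 0.19 and TUBB2A at 0.61 ± 0.16. COMMD7 (-0.92 ± 0.29), BCL2L2-PABPN1 (-0.59 ± 0.22), KLHL9 (-0.44 ± 0.16), ZNF772 (-0.39 ± 0.15) and CHML (-0.33 ± 0.11) were on the other side, HTT stood at -0.03 ± 0.23, and all of these had an adjusted p of 1.00. With edgeR 0 of 16750 genes passed, 215 had an unadjusted p under 0.05 and the smallest adjusted p was 0.286. DESeq2 called 20, of which 18 were higher in HD granules, and voom with quality weights called 5.

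Of the interferon response genes, IFI44 was at 0.553 CPM in control and 3.22 in HD granules (log2 fold change 2.51 ± 0.42, SE; adjusted p 0.764, 0.000112 with DESeq2 and 0.0139 with quality weights). IFIT2 stood at 1.46 ± 0.32 (0.0220 with DESeq2), and ANKRD1 had an adjusted p of 0.00280 with DESeq2. Of 25 interferon genes 17 had positive estimates, 0 were called and 2 passed when adjusted over the list alone (median 0.12; adjusted p 0.0241, and adjusted p 0.502 with an estimated correlation; median 0.07 and adjusted p 0.315 without HD granule 3).

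In the other granule lists no member was called, also when adjusted over the list alone, and 10 passed the test across lists. All 30 heat shock chaperones had positive estimates (median log2 fold change 0.27; adjusted p 1.55e-06, and adjusted p 0.798 with an estimated correlation), with HSPA1B at 1.06, HSPA1A at 1.04, BAG3 at 0.76 and STIP1 at 0.57. All 13 mitochondrial mRNAs did so too (median 1.15; adjusted p 3.49e-07, and adjusted p 0.798 with an estimated correlation), and their median was 0.22 without HD granule 3 (adjusted p 0.162), whose share of mitochondrial mRNA was 4.23%. Cytosolic ribosomal protein mRNAs had 67 of 79 positive (median 0.48; adjusted p 3.49e-07, and adjusted p 0.801 with an estimated correlation), and stress granule protein genes 39 of 43 (median 0.18; adjusted p 1.37e-05, and adjusted p 0.739 with an estimated correlation). Autophagy and lysosome genes had 28 of 34 (median 0.16; adjusted p 0.000251, and adjusted p 0.620 with an estimated correlation; median 0.11 and adjusted p 0.0922 without HD granule 3). Immediate early genes had 19 of 26 (median 0.15; adjusted p 0.00130, and adjusted p 0.798 with an estimated correlation; median 0.08 and adjusted p 0.372 without HD granule 3), and glycolytic genes 17 of 20 (median 0.30; adjusted p 0.0138, and adjusted p 0.801 with an estimated correlation; median -0.04 and adjusted p 0.456 without HD granule 3). Translation mRNAs with a 5' terminal oligopyrimidine tract had 20 of 25 (median 0.18; adjusted p 0.0357, and adjusted p 0.798 with an estimated correlation; median 0.15 and adjusted p 0.0662 without HD granule 3). Histones had 17 of 46 (median -0.13; adjusted p 0.00581, and adjusted p 0.801 with an estimated correlation), turning to a median of 0.12 without HD granule 3 (adjusted p 0.145). SnoRNAs and scaRNAs had 105 of 122 positive and a median of 0.39, yet the test across lists gave the opposite direction (adjusted p 0.00155, and adjusted p 0.801 with an estimated correlation), which turned to higher without HD granule 3 (median 0.73; adjusted p 3.31e-19, and unadjusted p 0.01002 with an estimated correlation). Without HD granule 3 a further 4 lists passed, the nuclear-encoded respiratory chain (median 0.57; adjusted p 2.36e-09), spliceosomal snRNAs (adjusted p 1.27e-05), mitochondrial ribosomal proteins (adjusted p 0.0137) and snoRNA hosts with cytoplasmic lncRNAs (adjusted p 0.0453). Their unadjusted p was 0.0506 to 0.475 with an estimated correlation.

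The difference between the HD effects of granules and exosomes was tested with an interaction term, and 3 of 16154 genes passed. PDCD6P1, a transcribed pseudogene of PDCD6 (chromosome 5, 1597557 to 1634005), had no read in control exosomes and was at least 54.5-fold higher in HD exosomes, with an interaction of -8.01 ± 1.03 (log2, SE; adjusted p 0.00913). ENSG00000290793 had no read in HD exosomes and was at least 15.9-fold higher in control exosomes (8.29 ± 1.17; adjusted p 0.0146). ENSG00000275895, which the annotation classes as an artifact, had no read in control exosomes and was at least 190-fold higher in HD exosomes (-11.17 ± 1.77; adjusted p 0.0429). HTT stood at -0.18 ± 0.36 (adjusted p 0.972). An unadjusted p under 0.05 was found for 778 genes, and DESeq2 called 12. ENSG00000275895 lost its call in 18 of 20 fits without 1 library (adjusted p 0.0618 to 0.156), with RLE size factors (0.0562), without a filter (0.317) and with a block of replicate numbers (0.264). ENSG00000290793 lost its call with that block (adjusted p 0.174), with DESeq2 (0.0896), in voom with quality weights (0.618) and without HD exosome 5 (0.0505), and PDCD6P1 with limma on log2(TPM + 1) (0.630). Without HD exosome 1, 28 genes passed, and without HD exosome 5, 1 passed. Across 13034 genes, which are not independent replicates, the HD effect in exosomes (without HD exosome 4) and in granules had a Pearson r of 0.11 and a Spearman rho of 0.08.

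**Figure D5:**
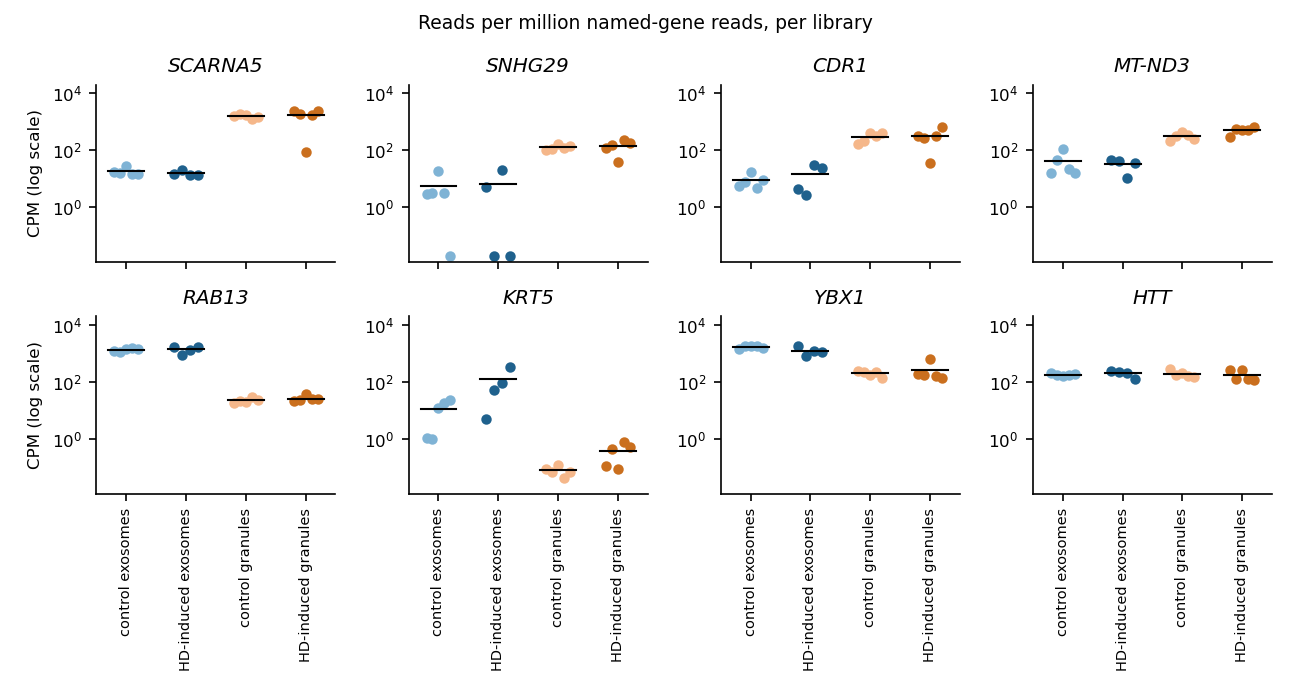
CPM of 8 genes in each library, without TMM scaling, on a log scale with zeros drawn at 0.02 CPM, a line at each group mean and HD exosome 4 left out. SCARNA5, SNHG29 and CDR1 were higher in granules, and RAB13, KRT5 and YBX1 in exosomes. With TMM scaling, HTT was at 183 CPM in control exosomes and 188 in control granules.

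Fold changes followed the GC content of transcripts. Across protein-coding genes the Spearman rho of the granule over exosome log2 fold change with GC content was -0.51 in control and -0.38 in HD-induced cells, and that of the HD effect was -0.65 in exosomes and -0.12 in granules. In control cells the median log2 fold change was 0.82 in the tenth of genes with the lowest GC content and -0.65 in the tenth with the highest. For the HD effect in exosomes these medians were 0.24 and -0.56. The list tests were not repeated with the GC correction that follows, so the part of GC content in any list result was not tested. With GC trends taken out per library, a correction chosen after the data were seen, 8940 of 14336 genes differed between compartments in control cells and 4953 of 13994 in HD-induced cells, and 0 passed for HD-induced against control in either compartment. Transcript length had a weaker relation to the compartment: its rho across genes was 0.0584 in control and 0.0526 in HD-induced cells with median transcript lengths, and 0.192 and 0.188 with the longest transcript of each gene.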

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

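All tests weighed here other than the interaction test, and the limit of 5% for the regroupings of libraries, were chosen after the results had been seen. Of 52 groups tested for a library far from the other 4, over 13 measures, 9 held one, where chance gives about 1 in 20 groups, or 2.6 of 52. HD exosome 4 had 544 genes with a read, against 14898 to 20500 in the other HD exosomes. HD exosome 2 had 9.90% of reads on nuclear-encoded mRNA, against 57.9% to 68.7%, and 86.6% on unnamed entries, against 29.3% to 38.6%, which also lay above all control exosomes at 36.7% to 46.3%. HD granule 3 had 4.23% on mitochondrial mRNA, against 0.605% to 0.783%. Control granule 2 had 0.592% on lncRNA, against 1.05% to 1.14%, and 0.134% on pseudogene transcripts, against 0.221% to 0.253%. Control exosome 5 had 0.212% on pseudogene transcripts, against 0.265% to 0.273%. Control exosome 1 had 1.20% on snRNA, against 0.639% to 0.754%, and HD granule 2 had 0.981%, against 0.0831% to 0.221%. The HD effects in granules and exosomes differed for PDCD6P1 (adjusted p 0.00913), ENSG00000290793 (0.0146) and ENSG00000275895 (0.0429).

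HD granule 3 lay apart from the other granule libraries. On a scale from 0 (exosomes) to 1 (granules) it stood at 0.408, against 0.902 to 1.17 in them. Its snoRNAs stood at 2.97% of the control granule level. HD exosomes 2 and 5 also lay in between on that scale, at 0.359 and 0.400, against -0.0987 to 0.0939 in control exosomes. Relative to the control exosome mean, levels in HD granule 3 had a rho with GC content of 0.0257. In the other granules it was -0.701 to -0.308. HD exosomes 2 and 5 were at -0.582 and -0.736, though control exosome 5, at -0.611, stood at a position of 0.0939. Whether GC-dependent recovery moved these positions was not tested. Exosome RNA mixed into HD granule 3 as the whole cause is argued against by 28 exosome-restricted genes. Their median level was 3.69% of the control exosome mean, against 0.613% to 1.87% in the other granules. Their summed level was 7.78%, against 1.39% to 2.73%, so a small amount stays open. An exchange with HD exosome 1, 2, 3 or 5 is argued against because those genes stood at a median of 29.8% or more there, while a single wrong label stays open, as does an exchange with HD exosome 4, which held only 13 reads on those genes (a summed level of 80.3%, a median of 0 and a position of 0.680). A loss of all nuclear RNA alike is argued against by 8 nuclear lncRNAs, whose ratios to the other HD granules had a median of 1.04 and ran from 0.376 (PVT1) to 227 (NEAT1), all far above the level of the snoRNAs. The ratios lay on both sides of 1, so the median does not mean that each was unchanged. NEAT1 averaged only 1.23 CPM in the other HD granules, with a lowest value of 0, and MIAT was at 0.223 CPM in HD granule 3 and 0.546 in the others. A different state of the cells in that culture was not tested.

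Fold changes followed GC content, which library preparation can change. GC-dependent recovery as the whole cause of the control compartment differences is argued against, as far as a gene's median GC content captures it. Of 5318 calls of at least 2-fold with GC values, 55.4% kept call, size and direction with GC trends taken out per library. Unrelated calls would share 14.03%, and 0 reached 2-fold the other way. Both sets of calls came from the same counts and could not be unrelated, so those 2 values decide nothing. The median log2 fold change of the 5318 calls, taken in the direction called, went from 1.57 to 1.11. GC content as part of the cause therefore stays open. The relation to GC content varied among control exosomes alone, whose rho against their own mean ran from -0.611 (replicate 5) to 0.616 (replicate 1). The rho of the HD effect in exosomes with GC content, -0.65, cannot be told apart from recovery that varied between libraries whatever their condition, as the GC slopes of 5 control and 4 HD exosome libraries gave an exact permutation p of 0.175, which does not show that they were alike, and a biological preference for transcripts by GC content was not tested.

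Keratinocyte transcripts were found in exosome libraries, at a sum over 30 of 31 markers (DSC3, at 48.2 CPM in granules, was left out as a gene these cells carry) of 20.0421 to 179 CPM in control exosomes and 48.1 to 1728 CPM in HD exosomes 1, 2, 3 and 5, against 4.52 to 13.7 CPM in granules. CPM values in this paragraph are without TMM scaling. Skin-cell RNA picked up during handling could be more visible where yield was low: over 9 exosome libraries the sum fell with named-gene reads (Spearman rho -0.883, permutation p 0.00308; Pearson r -0.828, permutation p 0.00562), and without the libraries farthest from the median, HD exosomes 2 and 3, r was -0.971 (permutation p 0.00198, n = 7). Release from HD-induced cells is the other explanation, and the sum gave an exact permutation p of 0.0794 between 5 control and 4 HD exosome libraries. The 2 cannot be told apart, because the 3 lowest counts of named-gene reads among the 9 were those of HD exosomes 2, 3 and 5. However, HD exosome 1, at 7.41 M reads on named genes, lay within the control range. Among controls the sum was 20.0421 and 27.1 CPM at the 2 highest such counts and 107 to 179 CPM at the 3 lowest. Named-gene reads stood in for yield here and are also the denominator of these CPM values. HD exosome 2 was low in them at 14.4 M estimated reads in all, as 86.6% lay on unnamed entries.

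Other groupings of the same libraries were tested for each gene count. For compartments in control cells 1 of 100 groupings, the real one, called 9227 genes and the highest other called 1, which is under the limit of 5%. Every other grouping mixed the compartments, which widens the spread within groups. The groupings therefore cannot tell what made the compartments differ. In HD-induced cells 3 of 100 called at least the real 2553. The highest other, 4833, set HD exosomes 1, 2, 3 and 5 with HD granule 3 against the rest, which points to a structure of the samples. That grouping is the one that an exchange of HD granule 3 with HD exosome 4, left open above, would give. For HD-induced against control the real count was 0, which every grouping reaches (100 of 100), so the groupings decide nothing there. The highest other was 1 in exosomes and 4503 in granules, the latter for control granules 1, 2 and 3 with HD granules 1 and 3, again a structure of the samples. For the interaction 4 of 60 called at least the real 3, with a highest other of 900, so chance is not excluded.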

How the results depend on the processing

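Chosen only after results were seen were the fits without the 3 doubted libraries (HD exosome 2, HD exosome 4 and HD granule 3), those without HD exosomes 2 and 4, the GC correction and the shares of named-gene reads; all other alternatives here were fixed earlier. Depth set a limit: HD exosome 4, with 713 reads on named genes, left no gene detected in both compartments once all 20 libraries were thinned to its depth (0 in control and 0 in HD-induced cells). Upper-quartile factors and thinning could not be fitted with HD exosome 4 for granules against exosomes in HD-induced cells, for HD-induced against control exosomes, or for the interaction. Where a count or direction changed below, the cause was not tested.

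The 9227 genes that differed between compartments in control cells stayed within 1.5 times in all alternatives but the 2-fold minimum, which left 5518 by its construction, and ranged from 8626 to 9544 over libraries left out in turn. The 2553 genes in HD-induced cells became 192 with limma on log2(TPM + 1), 6027 with voom quality weights, 4244 without a filter, 5661 in a fit of all 20 libraries, 4953 with the GC correction and 5758 without the doubted libraries. Leaving out single libraries gave 1.2e+03 (HD granule 2), 1240 (HD granule 5), 1349 (HD granule 4), 1477 (HD granule 1) and 5346 (HD granule 3). The 2402 shared calls became 600 at an adjusted p under 0.01 and 4979 without the doubted libraries, and ranged from 1177 (without HD granule 2) to 4967 (without HD granule 3).

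For HD-induced against control exosomes, where edgeR called 0 genes, DESeq2 called 2, limma on log2(TPM + 1) 22, a fit without a filter 275 and the fit of all 20 libraries 4, and counts ranged from 0 to 497 over libraries left out (497 without HD exosome 1). For granules DESeq2 called 20 and voom with quality weights 5, with 0 to 1 over libraries left out (1 without HD granule 4). The 3 interaction genes became 12 with DESeq2 and 0 with limma on log2(TPM + 1), with a minimum count of 50 or with protein-coding genes alone, and ranged from 1 (without HD exosome 5) to 28 (without HD exosome 1). Replicate numbers were not shown to pair libraries, so a block of them was an alternative only: it gave 4006 genes for compartments in HD-induced cells, 296 for exosomes, 1 for the interaction, and 0.0709 for HTT in HD-induced compartments.

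Of the list tests 33 passed with the preset correlation, 0 with an estimated correlation, 27 with fry, and 26 to 41 over libraries left out. Of 44 class tests 7 passed with shares of named-gene reads, and 0 to 7 over libraries left out (7 without HD granule 3). Genes detected in both HD-induced compartments, 391, became 1 at 10 expected counts and 8146 without the doubted libraries, and ranged from 391 to 4040 (without HD exosome 4). The rho with transcript length rose from 0.0584 to 0.105 with TPM-weighted lengths and 0.192 with the longest transcript in control cells, and from 0.0526 to 0.188 with the longest transcript in HD-induced cells.

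Single genes turned direction almost only where they had no call. HTT was called in none of the comparisons as reported. For compartments in control cells it ranged from -0.0798 (without control granule 1) to 0.21 (without control granule 4) and was -0.01 without control exosome 3. In HD-induced cells it was 0.12 with RLE factors and with DESeq2, 0.55 with limma on log2(TPM + 1), 0.0138 without a filter and 0.0261 without HD exosomes 2 and 4, and ranged from -0.18 (without HD granule 3) to 0.19 (without HD exosome 2), with positive values also without HD exosome 1 and HD granules 2, 4 and 5. For HD-induced against control it was -0.52 with limma on log2(TPM + 1) in exosomes and 0.0188 without a filter in granules, where it ranged from -0.13 (without HD granule 3) to 0.0939 (without control granule 1). Its interaction was 0.45 with limma on log2(TPM + 1) and ranged from -0.33 (without HD exosome 5) to 0.0150 (without HD exosome 2). In exosomes, limma on log2(TPM + 1) also gave -0.20 for NDUFAF2, -0.30 for HBG1 and -0.67 for HBA1, voom with quality weights -0.51 for HBA1, length-scaled counts 0.16 for H2AC25, and 1 surrogate variable -0.0269 for HBG1, -0.70 for HBB and -0.96 for HBA1. MT-ND5 in granules ranged from -0.0235 (without HD granule 3) to 3.24, and ANXA2, a called gene for HD-induced compartments, was at 0.13 with limma on log2(TPM + 1). With the GC correction HTT passed the threshold for compartments in control cells, at 0.35 (adjusted p 0.0291).

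Over the named genes, 1493 of 1498 alternative values for compartments in control cells kept direction and side of the threshold, as did 1451 of 1579 in HD-induced cells, 409 of 448 for exosomes, 550 of 561 for granules and 89 of 122 for the interaction. In HD-induced cells 105 values, in 55 genes, lost their call.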

Other observations

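The test described here was chosen after RAB13 and NET1 had been seen among the named genes, and so were the lists of unnamed entries. RAB13 and NET1 mRNAs are known to localise to the protrusions of migrating cells. In control cells RAB13 was at 1350 CPM in exosomes and 22.04 in granules (log2 fold change of granules over exosomes -5.93 ± 0.20, SE, n = 5 and 5), and NET1 at 2165 and 150 (-3.86 ± 0.14). Of 10 mRNAs with this localisation, all tested, 9 were higher in control exosomes and 6 in HD exosomes, and 0 were higher in granules. KIF1C stood at -5.57 ± 0.30, TRAK2 at -5.00379, KANK2 at -3.02, CYB5R3 at -2.26 and PKP4 at -2.05. A hypothesis is that mRNAs of cell protrusions may be carried in exosomes as a group. Leaving RAB13 and NET1 out, the other 8 had a median of -2.16. Over 10000 random lists matched in level and GC content it was -1.12 to 0.47, a percentile of 0, with none of the random lists as low. The random lists drew genes independently, which the 8 need not be, so the percentile can overstate the difference. Carriage of protrusion mRNAs as a group stays a hypothesis, since it was found and tested on the same libraries, and no control for vesicle origin is among them.

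Some unnamed entries differed between compartments by their share of reads. An entry of 290 nucleotides took 8.94% ± 0.644 (SD, n = 5) of control exosome reads and 0.163% ± 0.113 of control granule reads. A pair of 302 nucleotides took 6.86% each and 0.0604% each, 1 of 538 nucleotides 1.68% and 0.0227%, and 1 of 458 nucleotides 0.916% and 0.118%. On the granule side an entry of 298 nucleotides took 6.04% ± 0.780 of control granule reads and 0.128% ± 0.202 of control exosome reads, and 1 of 260 nucleotides 1.46% and 0.00124%. What these RNAs are is not given in the sources used here, and no test was made on these shares.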
